A study of Mus musculus with 9 samples.

How the data were processed

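RNA was sequenced from AML cells of 1 genotype taken from culture, bone marrow and lung, with 3 libraries per group and 9 in all. Per the labels, total RNA was isolated from few cells with a micro column kit, amplified with the SMART-seq v4 kit and made into libraries with the ThruPLEX kit. The authors demultiplexed with bcl2fastq and aligned with STAR to mm10 (versions not given in the sources used here), and the tool and annotation for counting are not given in the sources used here either. The deposited values are raw read counts per gene symbol, 55291 genes in each library, of which 30802 had reads in at least 1 library. Of these symbols 53292 occur in GENCODE M21, holding 99.1% of the reads, and coordinates come from that annotation (GRCm38). Where several genes share sequence, counts of a single paralog are uncertain.

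Depth ran from 27485111 to 38761363 counted reads per library. Genes with low counts were removed with filterByExpr, leaving 15066 genes that hold at least 99.9% of each library's reads; 81% of them are protein coding. Libraries were scaled with TMM (factors 0.966 to 1.039), and levels are CPM on the scaled library sizes, given as mean ± SD over n = 3. Each comparison (lung against bone marrow, bone marrow against culture, lung against culture) was a contrast in 1 edgeR 4.0.16 quasi-likelihood fit with robust dispersion on all 9 libraries in R 4.3.3. A gene passed at a Benjamini-Hochberg adjusted p under 0.05, and every adjusted p of a gene comes from this test. Standard errors are those of the log2 change. A ratio of genes with 3 or fewer reads in the lower group is given with an exact binomial interval at the 95% level, which covers counting error alone and treats amplified reads as independent, since its fitted change depends on the prior count.

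Before the data were examined, 35 gene lists were written for responses, cell states and markers of other cells. They were tested with camera of limma 3.58.1, with a preset correlation of 0.01 and with a correlation estimated per list, adjusting over the lists of a comparison. Counts of member genes are given over all genes tested and adjusted over the list alone. Genes were named by a rule also fixed beforehand. It takes the 8 largest rises and 8 largest falls among passing genes whose groups do not overlap and reach 10 CPM in the higher group, without predicted genes. It adds up to 2 passing members per direction of each response or state list (at 10 CPM), or the most abundant member where none passed. It also adds the 2 most abundant markers of each other cell type, and Trp53, Hba-a1 and Ptprc throughout. Genes outside the rule are said to be chosen after their values were seen.

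The pipeline was tested on simulated data with known changes. In each comparison 67, 67 and 66 genes were changed 1.5, 2 and 4-fold, all drawn from genes of 1 CPM or more. In lung against bone marrow the pipeline recovered 62.7%, 82.1% and 100% of them (42, 55 and 66 genes), with 13 false calls among 14689 genes. False calls are given against all genes run, and their share of the calls made is larger. In bone marrow against culture it recovered 59.7%, 83.6% and 98.5%, with 8 false calls among 14679 genes, and in lung against culture 70.1%, 86.6% and 97.0%, with 13 false calls among 14689 genes. Camera called the 1 changed list of 35 and 0 others in each comparison (simulated members were independent of each other). Apart from the changed genes, simulated groups shared the same mean and the same spread per gene. In the data the spread differed, with a median coefficient of variation of 4.2% in culture, 9.9% in bone marrow and 7.9% in lung. Recovery and false calls under such unequal spread were not tested. No 2 libraries of a group were duplicates. Chi-square per degree of freedom was 4.16 to 8.66 in culture, 30.82 to 44.87 in bone marrow and 16.11 to 30.22 in lung. This check cannot tell separate cultures or mice from repeated preparations of the same one.

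No label says whether libraries of the same number share a mouse or a day. Residuals of bone marrow and lung libraries of the same number correlated at 0.53, 0.43 and 0.37 over 6383 genes of 32 CPM or more, a limit chosen after the data were seen, and at 0.03, 0.27 and 0.09 over all tested genes. Bone marrow and lung libraries of different numbers correlated at -0.38 to 0.04 over the 6383 genes and at -0.24 to 0.14 over all tested genes. Culture libraries did not pair by number (-0.22 to -0.05 with tissue libraries of the same number over the 6383 genes). The numbers were therefore treated as a hint of pairing between bone marrow and lung, and the replicate block was run as an alternative.

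Alternatives comprised RLE, upper-quartile and library size scaling, no low-count filter and a stricter one (1 CPM in 6 libraries), DESeq2 1.42.0, limma-voom with quality weights, fits of 6 libraries alone, the replicate block, leaving out each library, thinning to the smallest library, glmTreat at 1.5-fold, dispersion without robust estimation, fry, and lists without markers of other cells. Added after the data were seen were the replicate block in bone marrow and lung alone, genes at 1 CPM or more in every culture library, and leaving out bone marrow replicate 3 and lung replicate 1 together. The shared response was compared with 20 simulations of unchanged groups. All libraries were used.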

Results

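RNA was sequenced from mouse acute myeloid leukaemia (AML) cells of the genotype Trp53(R172H/Δ), where R172H is a missense change in the tumour suppressor p53. The cells came from in vitro culture, from the bone marrow and from the lungs of wild-type recipient mice, with 3 libraries in each of the 3 groups. The series title names tissue-specific microenvironments as its subject. Lung against bone marrow therefore asks how these cells differ between tissues, and each tissue against culture asks how they differ from cells grown in vitro. Gene counts summed to 27485111, 33211032 and 29173102 reads in culture replicates 1 to 3. They summed to 33848551, 31444675 and 38761363 reads in bone marrow and to 38132239, 30075877 and 31850988 in lung. A single read corresponded to between 0.0258 and 0.0364 CPM (counts scaled to library size), and the 10 most abundant genes took between 2.48% and 3.78% of the reads.

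The 3 groups separated on the first 2 principal components of 15066 tested genes, which held 63% and 19.7% of the variance. The median coefficient of variation between replicates was 4.2% in culture, 9.9% in bone marrow and 7.9% in lung. Trp53 itself was measured at 295 ± 2.38 CPM in culture, 320 ± 30 CPM in bone marrow and 339 ± 38.9 CPM in lung (mean ± SD, n = 3). It passed the test in no comparison (adjusted p = 0.28, 0.078 and 0.54 for bone marrow against culture, lung against culture and lung against bone marrow). Ptprc, which encodes the leukocyte antigen CD45, was low in every group, at 1.62 ± 0.369, 7.13 ± 8.72 and 8.10 ± 2.08 CPM in culture, bone marrow and lung. Hba-a1, a haemoglobin alpha gene with a near-identical copy that makes its counts uncertain, was at 37.4 ± 1.47, 37.7 ± 11.9 and 59.0 ± 18.3 CPM.

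**Figure D1:**
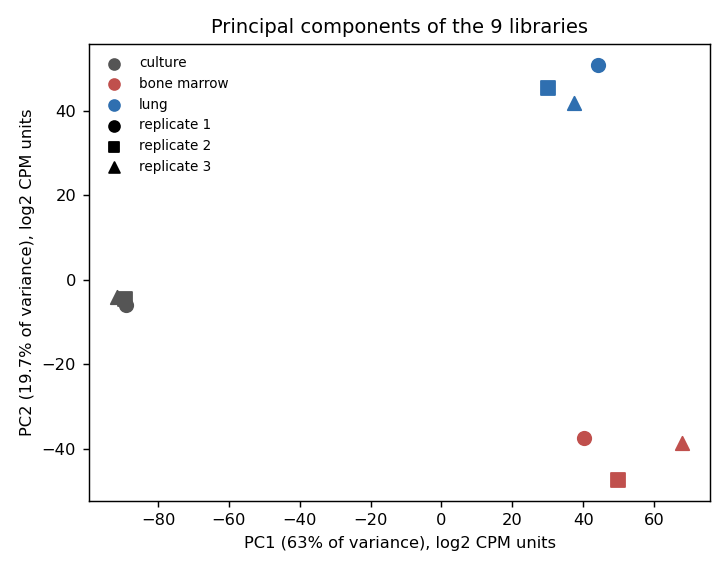
Position of each of the 9 libraries on the first 2 principal components of log2 CPM, with colour for the group and marker shape for the replicate number. The first axis (63% of the variance) parts culture from both tissues, and the second (19.7%) parts bone marrow from lung.

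Cells from lung carried far more RNA of immediate early genes, the rapid transcriptional response to stimulation or stress, than cells from bone marrow. Of the 20 measured members of that list, 17 rose and none fell (median log2 change 3.18; camera adjusted p = 3.5e-129, and 0.0044 with an estimated correlation). Fos, a subunit of the AP-1 transcription factor, was at 0.648 ± 0.151 CPM in bone marrow and 215 ± 39.8 CPM in lung, a log2 change of 8.34 ± 0.24 (SE; adjusted p = 1.4e-09). Fosb, of the same gene family, rose by 8.42 ± 0.27 on the log2 scale. Dusp1, a phosphatase that switches off MAP kinases, went from 5.41 ± 0.789 to 380 ± 65.9 CPM (log2 change 6.13 ± 0.15, adjusted p = 3.4e-11). Fos lies on chromosome 12 from 85473890 to 85477273 and Dusp1 on chromosome 17 from 26505590 to 26562128 (GRCm38). The heat shock members Hspa8 and Hspa1b, which the rule names in bone marrow against culture only, behaved differently. Hspa8 was at 1339 ± 277 CPM in bone marrow and 1573 ± 377 CPM in lung and did not pass the test (log2 change 0.23, adjusted p = 0.356). Hspa1b was at 16.91, 12.16 and 26.3 CPM in bone marrow replicates 1 to 3 and higher in lung, at 49.35, 46.58 and 66.75 CPM.

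Inflammatory genes downstream of NF-kB rose with them. In that list 11 of 16 measured members rose and none fell (median log2 change 2.32; camera adjusted p = 2e-22, and 0.012 with an estimated correlation). Tnfaip3, which encodes the NF-kB feedback inhibitor A20, was at 116 ± 19.6 CPM in bone marrow and 1847 ± 613 CPM in lung (log2 change 4 ± 0.23, adjusted p = 5.2e-06). The neutrophil chemokine Cxcl2 rose from 0.166 ± 0.0693 to 14.2 ± 3.80 CPM (log2 change 6.36 ± 0.34). Dusp18 and Tppp were also among the largest rises, by 7.07 ± 0.44 and 6.22 ± 0.43 on the log2 scale.

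**Figure D2:**
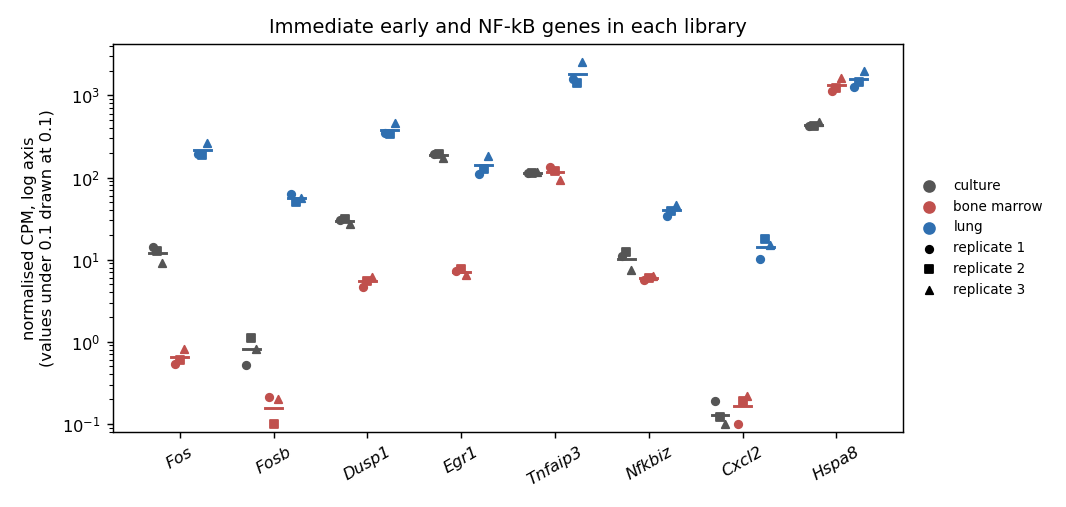
Normalised CPM on a log axis of 8 genes of the immediate early and NF-kB lists in each library, with points for libraries, marker shape for the replicate number and bars for group means. Fos averages 12.0 CPM in culture, 0.648 in bone marrow and 215 in lung, whereas the heat shock gene Hspa8 averages 439, 1339 and 1573 CPM. Hspa1b, a heat shock gene of the same list that is not drawn, is higher in every lung library than in every bone marrow library.

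Stress, interferon and lipid genes moved less far in lung. The integrated stress response and unfolded protein list had 12 of 20 members up and none down (median log2 change 0.45; camera adjusted p = 2.2e-09, and 0.032 with an estimated correlation). Among its members of 10 CPM or more in the higher group, Trib3 rose by 2.06 ± 0.14 and Ppp1r15a by 1.48 ± 0.11. Interferon gamma targets rose in 9 of 16 members (10 adjusted over the list alone), with Irf1 up by 1.32 ± 0.24 and Socs1 by 1.05 ± 0.13 on the log2 scale. The list's camera adjusted p was 4.2e-05 (adjusted p = 0.14 with an estimated correlation). Type I interferon genes rose in 7 of 22 members and fell in none (8 up and 1 down adjusted over the list alone), Oas3 by 1.34 ± 0.18 (camera adjusted p = 0.00098; adjusted p = 0.36 with an estimated correlation). Type I interferon members up numbered 13 without bone marrow replicate 3 and 11 with the replicate block, each with 1 down. The MHC class I presentation list had 8 of 15 members up and 1 down (camera adjusted p = 0.00098; adjusted p = 0.2 with an estimated correlation), and 5 up without lung replicate 2. Its H2-K1, a class I heavy chain that shares sequence with its paralogs, rose from 118 ± 14.0 to 247 ± 9.28 CPM, while the immunoproteasome subunit Psmb9 fell by 0.41 on the log2 scale. Cholesterol biosynthesis rose in 12 of 24 members and fell in none (15 up adjusted over the list alone) with a camera adjusted p of 8.2e-06 (adjusted p = 0.17 with an estimated correlation). Its Hmgcs1 rose by 0.97 ± 0.10 on the log2 scale.

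Regulators of growth and of stem cell identity also differed between the tissues. In the p53 target list 8 of 19 members rose and none fell (1 fell adjusted over the list alone; camera adjusted p = 0.001, adjusted p = 0.073 with an estimated correlation). Its cell cycle inhibitor Cdkn1a went from 1.64 ± 0.813 to 16.4 ± 4.80 CPM (log2 change 3.34 ± 0.31), below the 32.7 to 36.3 CPM of the culture libraries. In cells of the genotype Trp53(R172H/Δ), the list is not read as p53 activity in any comparison. TGF-beta targets had 6 of 15 members up and 2 down, with Ski up by 0.86 ± 0.11 and Id1 down by a log2 change of -0.83 ± 0.16 (camera adjusted p = 0.0023; adjusted p = 0.13 with an estimated correlation), a call lost with the stricter filter. Haematopoietic stem and self-renewal factors rose in 4 of 12 members and fell in none (5 up adjusted over the list alone; camera adjusted p = 0.0024, adjusted p = 0.094 with an estimated correlation), and 2 rose without culture replicate 1 or 2, bone marrow replicate 2 or lung replicate 1 or 2. Gata2 was at 52.3 ± 2.86 CPM in bone marrow and 186 ± 22 CPM in lung (log2 change 1.83 ± 0.09, adjusted p = 2.1e-08). Oxidative phosphorylation fell in 15 of 26 members and rose in none (16 down adjusted over the list alone; camera adjusted p = 6e-07, adjusted p = 0.26 with an estimated correlation). Each named member fell modestly, such as Ndufa4 (-0.55 ± 0.09). Proliferation genes fell in 8 of 25 members and rose in 1 (camera adjusted p = 0.0059; adjusted p = 0.67 with an estimated correlation), a call also lost with fry and without bone marrow replicate 1 (6 up and 7 down). The mitotic kinase Cdk1 changed by -0.69 ± 0.09. The 1 riser, the replication factor Mcm2 (0.32 ± 0.10), passed in 2 of the 9 fits that left out a library.

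Neutrophil granule genes were lower in lung, with wide spread between libraries. The secondary granule and neutrophil maturation list fell in 15 of 18 members (17 adjusted over the list alone; median log2 change -4.36; camera adjusted p = 6e-07, adjusted p = 0.4 with an estimated correlation). Ngp was at 89.9, 144 and 503.8 CPM in bone marrow replicates 1 to 3 and at 19.9, 2.44 and 2.62 CPM in the lung replicates, against 0.445 ± 0.232 CPM in culture. Camp changed by -5.03 ± 1.02 (adjusted p = 0.016) and the primary granule protease Elane by -5.46 ± 1.11 (adjusted p = 0.013) on the log2 scale. With the replicate block, 3 of the 18 members passed, and 9 named genes no longer did: Ngp, S100a8, S100a9, Lcn2, Ltf and Mpo (adjusted p from 0.055 to 0.07), Mmp8 (0.086), Chil3 (0.1) and Mmp9 (0.13). With the block in bone marrow and lung alone, Camp, Elane and Serpinb1a lost their calls too. Without lung replicate 2, and likewise without lung replicate 3, 2 secondary granule members passed, and for changes of more than 1.5-fold 0 did. The primary granule list had 5 of 10 members down and 1 up (6 and 2 adjusted over the list alone) and did not pass (camera adjusted p = 0.083), its Serpinb1a moving the other way, from 12.8 ± 9.01 to 120 ± 65.6 CPM. Of the primary granule genes 3 were down without lung replicate 2, without lung replicate 3 and with the replicate block, and 2 with the block in the 6 libraries alone. Monocyte and macrophage maturation genes had 4 of 16 members up and 2 down (3 down adjusted over the list alone; camera adjusted p = 0.94; 1 or 2 up without bone marrow replicate 1 or 2 or lung replicate 1 or 3), and Lyz2 at 126 ± 142 and 32.3 ± 18.4 CPM did not pass (adjusted p = 0.17).

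Markers of other cell types differed between the tissues as well. Not all of them are absent from cultured cells: the stroma marker Col1a2 was at 217, 131 and 178 CPM and the endothelium marker Calcrl at 193, 38.7 and 67.0 CPM in culture, bone marrow and lung. Endothelium markers rose in lung in 10 of 13 members (11 adjusted over the list alone; camera adjusted p = 2.6e-07, adjusted p = 0.17 with an estimated correlation). That call was lost with the stricter filter, where 3 of 5 members rose and the median log2 change was 0.78 instead of 3.80. Alveolar and airway epithelium markers rose in 3 of 6 (camera adjusted p = 0.0068; adjusted p = 0.2 with an estimated correlation). Leaving out lung replicate 3, or any 1 culture or bone marrow library, gave 5 to 7 such genes up, as more passed the filter. Fibroblast and stroma markers rose in 4 of 10 (camera adjusted p = 0.018; adjusted p = 0.46 with an estimated correlation), a call lost without lung replicate 1 (2 up) and without bone marrow replicate 1 or 3. T and NK cell markers rose in 5 of 8 (camera adjusted p = 0.00035; adjusted p = 0.13 with an estimated correlation), and 3 did without lung replicate 3. Resident tissue macrophage markers fell in 6 of 10 (9 adjusted over the list alone; camera adjusted p = 4e-06, adjusted p = 0.11 with an estimated correlation). The surfactant gene Sftpc had 2 reads in the 3 bone marrow libraries and 1967 in the 3 lung libraries, a ratio of 1040 with a 95% counting interval of 287 to 8590 that leaves out the spread between libraries. It was at 35.9, 8.25 and 10.9 CPM in lung replicates 1 to 3. Lists for B cells, dendritic cells, alveolar macrophages, megakaryocytes and erythroid cells did not pass (camera adjusted p = 0.58, 0.18, 0.56, 0.85 and 0.54).

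**Figure D3:**
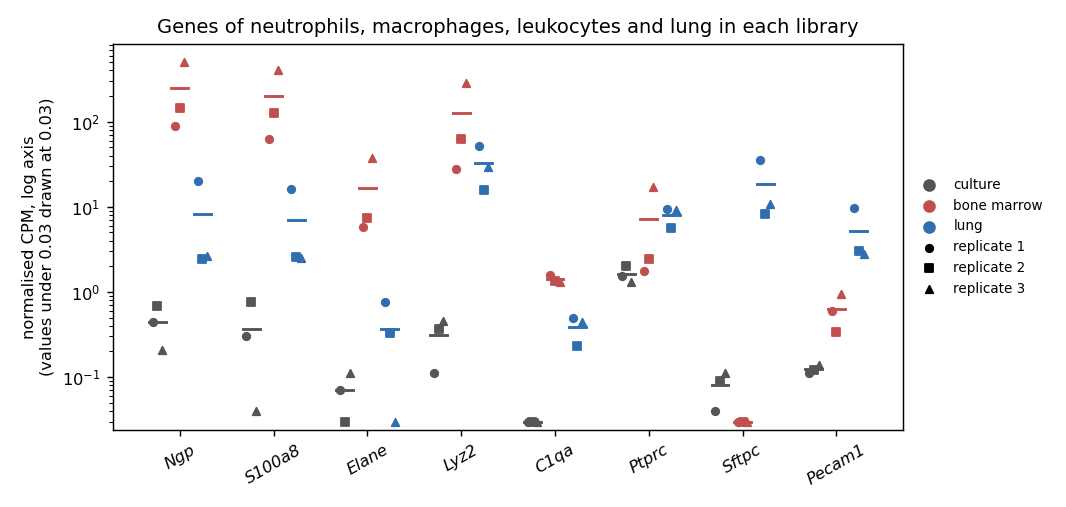
Normalised CPM on a log axis of 8 genes of neutrophils, macrophages, leukocytes and lung in each library, with points for libraries, marker shape for the replicate number and bars for group means; C1qa and Pecam1 were chosen after their values were seen. Ngp reaches 503.8 CPM in bone marrow replicate 3 and Sftpc 35.9 CPM in lung replicate 1, the highest library for each.

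Member counts adjusted over the list alone equal those over all genes wherever a single count is given here, for each comparison. In all, 3806 genes passed in lung against bone marrow, 2138 higher and 1668 lower in lung, of which 675 and 344 changed over 2-fold. The 6 libraries of the groups did not overlap in 36.6% of the genes, where chance gives 10%. Under upper-quartile scaling the split was 1796 higher and 2088 lower. The count was 476 for changes of more than 1.5-fold, 2381 when only these 6 libraries were fitted, 2414 without lung replicate 2 and 2473 without bone marrow replicate 2. Of 35 lists, 18 passed camera with its preset correlation and 3 with an estimated one (immediate early, NF-kB and integrated stress response). Regrouping the same 6 libraries called up to 19 lists with the preset and up to 1 with the estimate. Lists of glycolysis, hypoxia, MYC targets, MHC class II, lipid oxidation, glutathione, iron, adhesion, matrix and immune checkpoint genes did not pass (camera adjusted p from 0.095 to 0.81).

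Against culture, cells from bone marrow had much lower RNA of glycolysis and cholesterol biosynthesis genes. All 17 measured glycolysis genes fell (median log2 change -1.59; camera adjusted p = 2e-31, and 0.021 with an estimated correlation). Slc16a3, the lactate exporter MCT4, went from 288 ± 21.5 to 5.79 ± 2.51 CPM (log2 change -5.62 ± 0.26, adjusted p = 1.1e-07) and hexokinase 2 (Hk2) from 83.1 ± 3.25 to 5.66 ± 1.62 CPM (-3.87 ± 0.17). Cholesterol biosynthesis fell in 22 of 24 members and rose in 1 (median -1.90; camera adjusted p = 1.1e-33, and 0.013 with an estimated correlation), with Fdps at -3.26 ± 0.12 and the sterol sensor Insig1 at -3.06 ± 0.14. Hypoxia targets fell in 15 of 18 members and rose in 1 (16 down adjusted over the list alone; median -1.28; camera adjusted p = 2.1e-08, and 0.039 with an estimated correlation). Vegfa, the vascular growth factor, fell from 113 ± 13.9 to 1.25 ± 1.12 CPM and Bnip3, a mitophagy receptor, from 164 ± 11.2 to 7.38 ± 2.02 CPM. Hk2 lies on chromosome 6 from 82725025 to 82774454, Fdps on chromosome 3 from 89093588 to 89101959 and Vegfa on chromosome 17 from 46016993 to 46032369 (GRCm38).

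The integrated stress response list fell in 15 of 20 members and rose in 2 (median log2 change -1.25; camera adjusted p = 2.2e-15, and 0.013 with an estimated correlation). Slc7a11, the cystine transporter, changed by -7.03 ± 0.22 (adjusted p = 7e-11), from 43.2 ± 2.24 to 0.318 ± 0.163 CPM, and the glutathione-degrading enzyme Chac1 by -5.00 ± 0.25, while the chaperone Hyou1 rose by 1.04 ± 0.11. The cationic amino acid transporter Slc7a3 (-7.22 ± 0.21), Kcnh1 (-6.58 ± 0.27), Cox6a2 (-6.52 ± 0.31), Chst1 (-6.49 ± 0.20), Emp2 (-6.43 ± 0.43) and Chd5 (-6.30 ± 0.67) were the other largest falls beside Vegfa. In the p53 target list 9 of 19 members fell and 4 rose (camera adjusted p = 0.043; adjusted p = 0.2 with an estimated correlation), a call lost without bone marrow replicate 1. Cdkn1a changed by -4.42 ± 0.32 and Sesn2 by -3.88 ± 0.12, but Aen by 1.13 ± 0.15. Immediate early genes fell in 16 of 20 members and rose in 3 (median -1.69; camera adjusted p = 3.2e-09, adjusted p = 0.2 with an estimated correlation). Egr1 changed by -4.71 ± 0.19 and Fos by -4.19 ± 0.25, but Hspa8 by 1.61 ± 0.18. Stem and self-renewal factors fell in 7 of 12 and rose in 2 (camera adjusted p = 0.042; adjusted p = 0.2 with an estimated correlation), a call lost in 9 alternatives. Gata2 fell from 299 ± 2.63 to 52.3 ± 2.86 CPM.

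Ribosome biogenesis, antigen presentation and interferon genes rose in bone marrow. All 22 MYC target and ribosome biogenesis genes rose (median log2 change 0.77; camera adjusted p = 3.1e-11, adjusted p = 0.16 with an estimated correlation), with Bop1 up by 1.54 ± 0.09. Oxidative phosphorylation rose in 20 of 26 (21 adjusted over the list alone; median 0.43; camera adjusted p = 4.2e-05, adjusted p = 0.45 with an estimated correlation), cytochrome c (Cycs) by 0.95 ± 0.09. Type I interferon genes rose in 17 of 22 and fell in 2 (median 2.08; camera adjusted p = 6.2e-07, adjusted p = 0.2 with an estimated correlation). Irf7, the master regulator of that response, went from 4.09 ± 0.343 to 21.6 ± 0.653 CPM (log2 change 2.40 ± 0.16) and Cmpk2 from 1.33 ± 0.161 to 29.3 ± 6.32 CPM, whereas Ifit2 changed by -0.69 ± 0.14. MHC class I presentation rose in 13 of 15 and fell in 1 (camera adjusted p = 9.4e-06; adjusted p = 0.16 with an estimated correlation): Psmb10 rose by 2.29 ± 0.12 and H2-K1 changed by -1.11 ± 0.09. Cxcr4, a chemokine receptor, rose from 0.535 ± 0.330 to 11.4 ± 1.25 CPM, and likewise to 12.5 ± 6.78 CPM in lung (log2 changes 4.45 ± 0.51 and 4.58 ± 0.51), although the adhesion list as a group did not pass (8 of 22 up and 8 down; camera adjusted p = 0.89). Proliferation genes fell in 15 of 25 and rose in 5 (16 down adjusted over the list alone; camera adjusted p = 0.043, adjusted p = 0.86 with an estimated correlation), a call lost in 9 alternatives. Mki67 changed by -1.65 ± 0.16 and Tyms by 0.99 ± 0.07.

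Myeloid maturation genes rose in bone marrow, the 18 measured secondary granule genes being between 5.21 and 16.0 times as high in replicate 3 as in replicate 1. All 18 secondary granule genes rose (median log2 change 9.02, or 8.43 with the 7 members of 3 or fewer culture reads held at 3 reads; camera adjusted p = 0.00018, adjusted p = 0.66 with an estimated correlation). Ngp, S100a8 and S100a9 averaged 246 ± 225, 199 ± 185 and 194 ± 185 CPM. Primary granule genes rose in 9 of 10 (10 adjusted over the list alone; camera adjusted p = 0.024, adjusted p = 0.66 with an estimated correlation). Mpo had 2 reads in culture and 3102 in bone marrow, a ratio of 1280 (95% counting interval 354 to 10600), and Mmp8 had 2 and 2107, a ratio of 869 (240 to 7180); these intervals cover counting error alone, and Mpo was at 11, 12.2 and 58.1 CPM in bone marrow replicates 1 to 3. Monocyte genes rose in 13 of 16 (14 adjusted over the list alone; camera adjusted p = 0.0054, adjusted p = 0.66 with an estimated correlation), a call lost with the stricter filter, and resident macrophage markers in 8 of 10 with 1 down (camera adjusted p = 0.00048; adjusted p = 0.2 with an estimated correlation). Ptprc, at 1.78, 2.41 and 17.2 CPM in bone marrow replicates 1 to 3, was also highest in replicate 3.

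In bone marrow against culture 9116 genes passed, 4626 higher and 4490 lower, of which 1890 and 1833 changed over 2-fold, and 3916 passed for changes of more than 1.5-fold. Groups did not overlap in 67.2% of genes (10% by chance). Of 35 lists 16 passed with the preset correlation and 4 with an estimated one (glycolysis, cholesterol, integrated stress response and hypoxia). Regrouping of the 6 libraries called up to 16 and 0 lists. MHC class II, interferon gamma, lipid, NF-kB, TGF-beta, glutathione, iron, matrix and immune checkpoint lists did not pass (camera adjusted p from 0.068 to 0.78). Nor did the epithelium, endothelium, stroma, alveolar macrophage, B cell, T and NK cell, erythroid, megakaryocyte and dendritic cell markers (0.26 to 0.98).

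Cells from lung shared the metabolic falls. Glycolysis fell in 16 of 17 members against culture (17 adjusted over the list alone; median log2 change -1.53; camera adjusted p = 6e-36, and 0.022 with an estimated correlation) and cholesterol biosynthesis in 22 of 24 with 1 up (median -1.62; camera adjusted p = 6.6e-29, and 0.024 with an estimated correlation). Slc16a3 (-4.88 ± 0.25), aldolase C (Aldoc, -2.99 ± 0.14), Fdps (-2.88 ± 0.12) and Msmo1 (-2.44 ± 0.11) were among the falls. The integrated stress response list fell in 13 of 20 and rose in 3 (camera adjusted p = 7.1e-09, and 0.032 with an estimated correlation), with Slc7a11 at -5.71 ± 0.20 and the chaperone Hspa5 at 0.58 ± 0.10. Hypoxia targets fell in 14 of 18 and rose in 1 (camera adjusted p = 7.8e-09; adjusted p = 0.051 with an estimated correlation), with Bnip3 at -5.04 ± 0.18 and Vegfa at -3.55 ± 0.36. The remaining largest falls were those of Chst1 (-5.13 ± 0.18), Slc7a3 (-5.11 ± 0.18), Ndufa4l2 (-4.70 ± 0.31), Arhgap20 (-4.64 ± 0.28) and Chd5 (-4.54 ± 0.57). Proliferation genes fell in 13 of 25 and rose in 3 (4 up adjusted over the list alone, 5 up without bone marrow replicate 1; camera adjusted p = 6.5e-05, adjusted p = 0.53 with an estimated correlation), Mki67 changing by -1.50 ± 0.16. The glutathione list had 5 of 16 up and 5 down, from Me1 at -2.81 ± 0.11 to Txnrd1 at 0.89 ± 0.09 (camera adjusted p = 0.031; adjusted p = 0.14 with an estimated correlation), a call lost in 3 alternatives, with 3 up without lung replicate 2.

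Immune and stimulus genes rose in lung against culture. MHC class I presentation rose in 14 of 15 (median log2 change 1.31; camera adjusted p = 4.1e-12, and 0.032 with an estimated correlation), with Psmb10 at 2.18 ± 0.12 and Erap1 at 1.74 ± 0.10. Type I interferon genes rose in 18 of 22 and fell in 1 (median 3.14; camera adjusted p = 5.3e-13, adjusted p = 0.088 with an estimated correlation), with Cmpk2 at 4.79 ± 0.19 and Usp18 at 4.61 ± 0.21. Interferon gamma targets rose in 13 of 16 (14 adjusted over the list alone; camera adjusted p = 8.1e-06, adjusted p = 0.11 with an estimated correlation). NF-kB genes rose in 12 of 16 and fell in 1 (13 up adjusted over the list alone; camera adjusted p = 3.1e-06, adjusted p = 0.081 with an estimated correlation), Tnfaip3 by 4.03 ± 0.23 and Cxcl2 by 6.77 ± 0.36. Immediate early genes rose in 15 of 20 and fell in 1 (16 up adjusted over the list alone; median 1.54; camera adjusted p = 3.2e-16, adjusted p = 0.094 with an estimated correlation), with Fosb at 6.08 ± 0.22 and Fos at 4.16 ± 0.18. MYC target and ribosome biogenesis genes rose in 21 of 22 (camera adjusted p = 2.1e-15; adjusted p = 0.081 with an estimated correlation), Bop1 by 1.71 ± 0.09. Myadm (7.68 ± 0.69), the transcription factor Klf2 (6.62 ± 0.62), Lyz2 (6.65 ± 1.51), Scin (6.44 ± 1.20), Tppp (6.32 ± 0.45) and Sftpc (7.78 ± 0.84) were the other largest rises.

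Markers of maturation and of other cells moved in lung too. Monocyte genes rose in 13 of 16 and fell in 1 (14 up adjusted over the list alone; camera adjusted p = 0.00093, adjusted p = 0.53 with an estimated correlation), a call lost with the stricter filter. Matrix and coagulation genes rose in 7 of 13 (camera adjusted p = 0.0099; adjusted p = 0.53 with an estimated correlation), and 11 of 15 did without bone marrow replicate 1. Endothelium markers rose in 11 of 13 with 1 down (camera adjusted p = 0.0071; adjusted p = 0.52 with an estimated correlation) and stroma markers in 6 of 10 (camera adjusted p = 0.046; adjusted p = 0.56 with an estimated correlation), calls lost with the stricter filter for endothelium and in 5 alternatives for stroma. T and NK cell markers rose in 7 of 8 with 1 down (camera adjusted p = 0.023; adjusted p = 0.42 with an estimated correlation). Of 18 secondary granule genes 2 rose and 0 adjusted over the list alone (camera adjusted p = 0.025; adjusted p = 0.64 with an estimated correlation). This count depends on the fit: 14 without bone marrow replicate 3, 5 without bone marrow replicate 1, 0 without any 1 culture library, 12 of 12 tested with only the 2 groups, 13 without robust dispersion and 15 of 19 with DESeq2. Ngp did not pass (adjusted p = 0.072). The stem factor Kit changed by -0.89 ± 0.13, while its list did not pass (2 of 12 up and 5 down; camera adjusted p = 0.4). Oxidative phosphorylation, MHC class II, p53, TGF-beta, lipid, iron, primary granule, adhesion and immune checkpoint lists did not pass either (camera adjusted p from 0.06 to 0.64). Nor did epithelium, alveolar and resident macrophage, B cell, erythroid, megakaryocyte and dendritic cell markers (0.064 to 0.56).

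**Figure D4:**
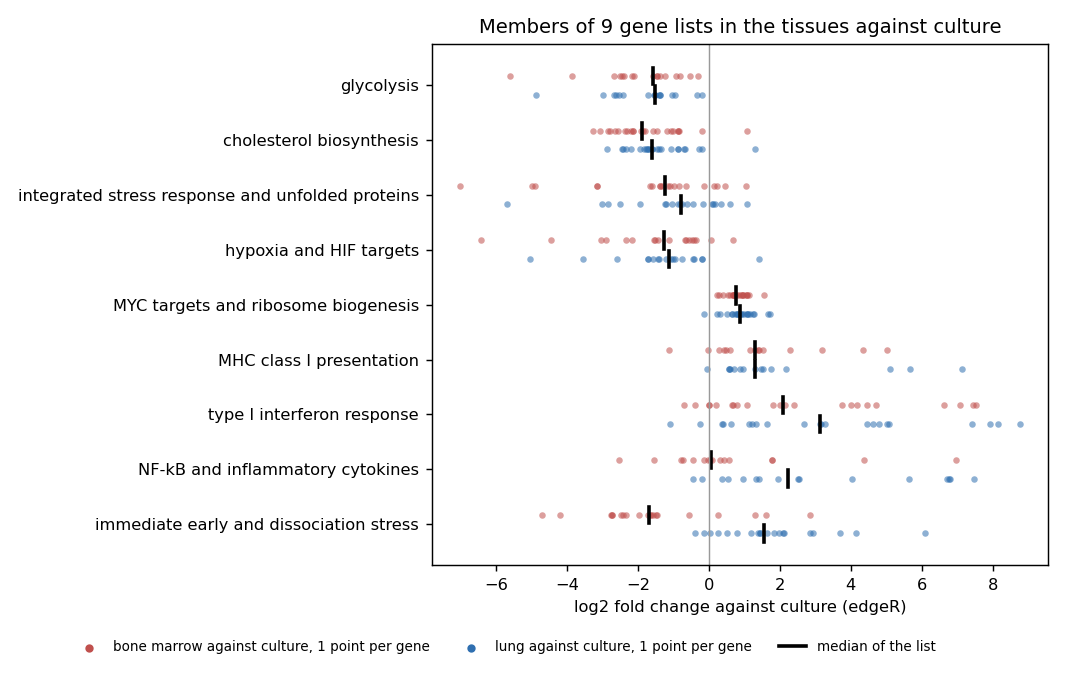
Log2 fold change against culture of each measured member of 9 gene lists, in bone marrow (red) and lung (blue), with a black bar at the median of each list; changes of genes with few culture reads depend on the prior count. Glycolysis has medians of -1.59 and -1.53 in bone marrow and lung, and the immediate early list of -1.69 and 1.54.

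Altogether 8271 genes passed in lung against culture, 4204 higher and 4067 lower, of which 1597 and 1528 changed over 2-fold, and 3144 passed for changes of more than 1.5-fold. Groups did not overlap in 66.8% of genes (10% by chance). Of 35 lists 18 passed with the preset correlation and 4 with an estimated one (glycolysis, cholesterol, integrated stress response and MHC class I). Regrouping of the 6 libraries called up to 21 and 0 lists. Both tissues changed 6492 genes in the same direction against culture, 3234 up and 3258 down, where independent lists would share 1291 and 1212, and 105 genes went opposite ways. Log2 changes correlated across genes at 0.84, with genes not being independent replicates, and their covariance was 1.88. Over the 8746 genes of 10 CPM or more on average, the correlation was 0.85 and the covariance 0.50. Unchanged groups simulated 20 times against the same culture means shared 0.1 genes on average. That count is low by design, as no gene was changed in them, so it cannot judge the overlap of 6492 genes. The simulated groups had a correlation of 0.51 and a covariance of 0.0357 over all genes, a covariance difference of 1.84. Error of the shared culture libraries is in these simulations at the fitted spread. The 3 culture libraries are too few to be split, so part of the excess may still come from shared error beyond it.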

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

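The tests of RNA from lung cells and of handling in this part were chosen after the result was seen. A difference between bone marrow and lung drew attention here: 105 genes passed in opposite directions against culture with the difference between the tissues passing too (edgeR), and 91 of them were higher in lung and lower in bone marrow. The immediate early list had medians of -1.69 in bone marrow and 1.54 in lung. Among named genes these were Dusp1 (-2.43 and 3.70 on the log2 scale), Fos (-4.19 and 4.16), Fosb (-2.35 and 6.08), Nfkbiz (-0.78 and 1.96) and Ski (-0.54 and 0.32), each from 3 libraries per group. All 5 differences passed in lung against bone marrow, as that contrast is the difference between the tissues.

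Immediate early genes respond within minutes, so their rise in lung has technical candidates. RNA from cells of the lung may contribute. The summed lung excess over bone marrow of 149 markers of other cells was 308.6 CPM, or 9.98% of the 3091 CPM excess of the list. That is practically at the limit of 10% below which this source was to be set aside. The share was 8.72%, 8.80% and 14.0% without lung replicate 1, 2 or 3. The sum also counts markers that cultured cells express, such as Col1a2 (209 to 222 CPM in the culture libraries) and Calcrl (177 to 213 CPM). It is therefore not a measure of lung-cell RNA alone, and the test leaves this source open. In lung replicate 1, 18 markers of lung epithelium, endothelium and stroma were at a median of 3.15 times the mean of replicates 2 and 3, and 19 immediate early members at 0.87 times, which 1 library alone does not settle. Handling during isolation cannot be told apart from the tissue: 17 of 20 members were higher in every lung library than in every bone marrow library, and tissue and isolation coincide in this design. A response of the leukaemia cells to the lung itself stays open too, and was not tested.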

How the results depend on the processing

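The alternatives chosen after the data were seen were the replicate block in bone marrow and lung alone, genes at 1 CPM in culture, and leaving out bone marrow replicate 3 and lung replicate 1 together. No named gene that passed changed sign while passing under the alternatives run. The majority among passing genes in lung against bone marrow did turn with upper-quartile scaling, from 2138 higher and 1668 lower in lung to 1796 higher and 2088 lower. With glmTreat at 1.5-fold the genes passing were 476, 3916 and 3144 (lung against bone marrow, bone marrow against culture, lung against culture) and the shared response 2321, since that test asks for a larger change. In lung against bone marrow 2381 genes passed with only the 2 groups fitted, an alternative with fewer samples and without culture. Such fits gave 8852 genes in bone marrow against culture (reported 9116) and 8823 in lung against culture (reported 8271), so fewer samples need not lower the count. The reported fit shares its estimate of spread with culture, where the median coefficient of variation was 4.2%, against 9.9% in bone marrow and 7.9% in lung. Whether this raised the reported count was not tested. Leaving out single libraries gave from 2414 (without lung replicate 2) to 4760 (without bone marrow replicate 1), with 2473 without bone marrow replicate 2.

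The number of lists passing fell to 3, 4 and 4 with an estimated correlation. It was 11 in lung against bone marrow and 11 in lung against culture with the stricter filter, which tests fewer genes, and 30 in lung against culture with fry; for fry the cause was not tested. Leaving out single libraries gave 17 to 22, 14 to 16 and 19 to 22 lists.

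The remaining gene counts stayed within 1.5 times the reported ones: RLE 3816, 9117 and 8289, library size alone 3787, 9203 and 8310, no filter 4477, 9747 and 9116, DESeq2 4192, 9219 and 8523, and voom 3560, 9456 and 9477. Thinning to the smallest library, which tests the limit set by depth, gave 3706, 8939 and 8069. Upper-quartile scaling moved the median log2 change of all genes in bone marrow against culture to 0.12 (reported fit 0.048), and made 46.2% of passing genes higher in lung than in bone marrow, against 56.2%. The replicate block gave 4133, 9228 and 8433 genes, and 4553 in the paired fit of bone marrow and lung alone.

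Named genes in lung against bone marrow lost 9 of 67 calls with the replicate block, 12 with it in the 6 libraries alone, 19 with only the 2 groups, 21 without lung replicate 2 and 43 with glmTreat. Against culture the block ended 1 of 93 calls in bone marrow and 2 of 89 in lung. Of the 18 secondary granule genes, 15 passed as lower in lung, 3 with the block and 0 with the block in the 6 libraries alone, where the list median was -4.07 (reported -4.36); the cause was not tested.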

Other observations

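The tests of host myeloid RNA, maturation, dilution, depth and scaling in this part, and the counts of lists with an estimated correlation among other splits, were chosen after the results were seen. Other splits of the 6 libraries of each comparison number 10 with the real one, too few for a share under 0.05. In lung against bone marrow the real split called 3806 genes and the highest other 1, in bone marrow against culture 9116 and 0, and in lung against culture 8271 and 0 (edgeR), so that in each 1 split of 10 reached the real count. For lists with the preset correlation, 4, 2 and 7 of the 10 splits called as many as the real 18, 16 and 18, the highest others being 19, 16 and 21. With an estimated correlation the real splits called 3, 4 and 4 lists and the highest others 1, 0 and 0. In the report, a list passes or loses its call by the preset correlation, and the value with an estimated correlation stands beside each list that passed. Among the 4 splits that part every pair of equal numbers, the highest other counts of genes were 1, 0 and 0.

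Neutrophil granule genes in bone marrow may come from host myeloid cells. Over the 18 measured members the ratio of replicate 3 to replicate 1 had a median of 6.69, from 5.21 to 16.0, with an SD of 0.45 on the log2 scale, as a single varying source would give. Ptprc rose with them by 9.64 times (1.78, 2.41 and 17.2 CPM in replicates 1 to 3), and the members' median in culture was 0.068 CPM. Maturation of some leukaemia cells would scale the members and Ptprc together as well, so it cannot be told apart by this ratio. The sort gate is not given in the sources used here.

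Lower glycolysis and cholesterol genes in both tissues were set against 3 technical explanations. Dilution by host RNA would lower genes that host cells do not express. The 8738 genes of 10 CPM or more in culture had a median log2 change of -0.008 in bone marrow and 0.005 in lung without a composition factor. Host cells may express many of these genes too, so a median near 0 cannot decide on dilution. Thinning to equal depth moved the medians of the lists by up to 0.01, and under other scalings the median nearest 0 was -1.49. The values after thinning and under other scalings argue against unequal depth and scaling as the whole cause, and dilution stays open. A response of the cells to leaving culture may be the source, as a hypothesis found and examined on the same data.

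Erythroid genes, chosen here after their values were seen, included abundant ones in all 3 groups: Klf1 averaged 306, 301 and 288 CPM and Epor 131, 179 and 165 CPM in culture, bone marrow and lung. Slc4a1 averaged 0.43, 4.76 and 12.0 CPM. Ighm was at 317 CPM in culture, at 50.0, 6.96 and 77.6 CPM in bone marrow and at 60.7, 12.1 and 86.2 CPM in lung replicates 1 to 3, with the lowest value in replicate 2 of both tissues. Car1 was at 1476, 1388 and 539 CPM in bone marrow and at 840, 681 and 397 CPM in lung.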
